A study of Mus musculus with 16 samples.

How the data were processed

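Heart tissue RNA of 16 male mice was sequenced in 4 groups of 4, Ppara-flox or cardiomyocyte PPARα-deficient, each given PBS or LPS, with stranded libraries per the labels. The label text on RNA extraction speaks of pancreatic islets while tissue, source and design name the heart. In the files the islet genes Ins1 and Ins2 had 0 counts in all 16 libraries and Myh6 was at least 17239 CPM in each, and the libraries were taken as heart. The Cre line is not named in the labels. The submitters' processing notes name fastp 0.23.2, HISAT, StringTie 1.3.3b, DESeq2 1.30.1 and the genome build GRCm38, without saying which tool made the counts, from which annotation or with which strand setting.

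Each deposited table holds expected counts (estimated counts), whole numbers per gene symbol, not scaled between samples. Among low values the number 4 occurred 12837 times, against 5293 for 3 and 7268 for 5, and 10 of the 10 multiples of 4 up to 40 exceeded both neighbours. Other values occurred too, such as 1 in 9566 entries. A read pair was therefore taken to count as about 4, which was not tested. On this reading counting precision follows from each total divided by 4 (16392284 to 18859006) and not from the total (65569134 to 75436023). A floor of 12 estimated counts (3 read pairs) per library was used for groups at 0. Of 55421 table lines, 27 carried symbols turned into dates by a spreadsheet and were left out (0.0644% to 0.0861% of a library's counts), and 112 repeated symbols were summed, leaving 55278. Coordinates and gene types came from GENCODE vM21 on GRCm38, which held 53543 of the symbols.

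The tests were run with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and figures with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Genes were kept by filterByExpr on the 4 groups (18713 genes), scaled by TMM factors and fitted with glmQLFit as 4 group means over all 16 libraries (12 residual degrees of freedom). Each comparison was an F test (glmQLFTest) with Benjamini-Hochberg adjustment, called at an adjusted p under 0.05 without a fold minimum. The standard error of a log2 fold change is its size divided by the root of F. The interaction is the LPS effect in PPARα-deficient hearts minus that in Ppara-flox hearts. Principal components used the 1000 most variable genes on the log2 CPM scale.

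Gene lists were fixed before the data were examined. The 39 lists with at least 3 measured members were tested with camera on voom values at a preset inter-gene correlation of 0.01, adjusted over the lists within each comparison, then again with the correlation estimated from the data and with fry, which tests whether a list's genes move on balance one way without comparing them with other genes. List counts were made over all genes and adjusted over the list alone.

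The rule for named genes, fixed before the data were examined, took Ppara in each comparison, then up to 10 genes with the highest and 10 with the lowest log2 fold change among called genes with an average of at least 2 on the log2 CPM scale and no overlap between the compared groups, leaving out gene models without an ordinary symbol. It then took up to 4 members with the smallest adjusted p of each list described (2 with the smallest p where none passed). Under it 157 genes were named. The text leaves out most of those whose calls rest on single libraries. Levels of a gene named in 1 comparison are also given in others.

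Alternatives fixed beforehand were RLE and upper-quartile factors, DESeq2's Wald test, no filter and a stricter filter (at least 1 CPM in 8 libraries), an adjusted p under 0.01, a 2-fold minimum, a fit to the 8 libraries compared, the replicate number as a block and leaving out each library in turn. Chosen after seeing the data were counts divided by 4, edgeR's bias-adjusted deviances, limma-voom, leaving out Ppara-flox LPS replicate 4 and PPARα-deficient LPS replicate 3 together, the 2 number series among the PBS libraries as a block, and leaving out mitochondrial genes with 5 nuclear models like them. Between genotypes the inflammatory list was also tested without each library in turn, as were the interferon and macrophage lists after LPS, there also without the 2 libraries together, again chosen after seeing the data. The model was tested on simulated data with the spread of these libraries. Each simulation changed 66 or 67 genes per size, all averaging at least 1 CPM. Recovery with as many changed genes as LPS gave was not simulated. In the 4 group comparisons the model recovered 13.6% to 27.3% of genes changed by 0.5 on the log2 scale. It recovered 65.7% to 74.6% of those changed by 1 and 95.5% to 98.5% of those changed by 2. For the interaction these were 6.1%, 43.3% and 77.6%. False calls were 2.3% for the interaction and 3.8% to 6.4% in the group comparisons.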

Results

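RNA was sequenced from heart tissue of male C57BL/6J mice aged 8 to 12 weeks. The mice carried floxed Ppara alleles alone (Ppara-flox) or lacked PPARα in their cardiomyocytes (PPARα-deficient). Each genotype received lipopolysaccharide (LPS, a bacterial endotoxin used to model sepsis) at 5 mg/kg into the peritoneum, or phosphate-buffered saline (PBS), and hearts were taken after 12 h. There were 4 mice in each of the 4 groups and 16 libraries in all. PPARα, the product of Ppara, is a nuclear receptor that switches on genes for fatty acid uptake and oxidation, and the series was designed around its part in the septic heart and in mitochondrial function. The deposited estimated counts summed to 65569134 to 75436023 per library, and 20762 to 21506 gene symbols had a count in each. Low values piled up at multiples of 4, so each total divided by 4, 16392284 to 18859006, was taken as nearer to the number of read pairs counted. Transcripts encoded by the mitochondrial genome took 22.5% to 29.8% of the counts. Floors cover counting error only, while the values given after ± include the spread between libraries. Fold changes below are log2 values from the edgeR quasi-likelihood model with their standard error (SE, n = 4 per group). Levels are in CPM, counts scaled by the TMM library size, with the SD over 4 libraries. Adjusted p-values are Benjamini-Hochberg values from that model, and coordinates are GRCm38.

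LPS separated the libraries along the first principal component, which held 57.1% of the variance of the 1000 most variable genes, against 5.0% for the second. Myh6, the gene of the main cardiac myosin heavy chain of the adult mouse, fell with LPS in both genotypes, from 35610 ± 1627 to 19330 ± 1713 CPM in Ppara-flox hearts and from 32950 ± 2592 to 19480 ± 1397 CPM in PPARα-deficient hearts.

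**Figure D1:**
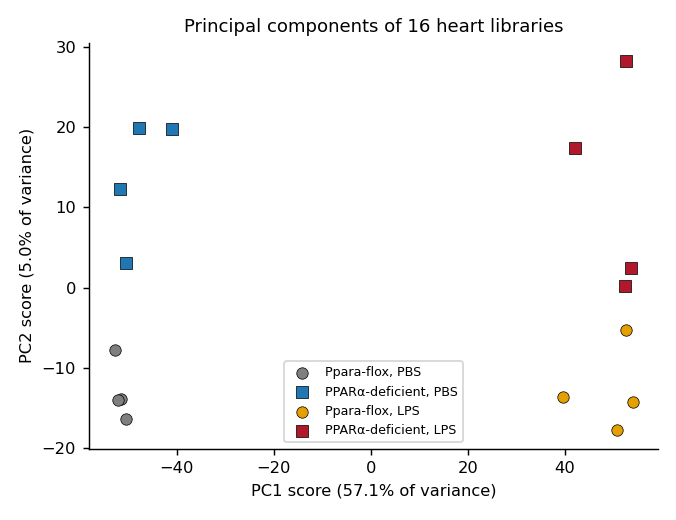
Scores of the 16 libraries on the first (57.1% of variance) and second (5.0%) principal components of the 1000 most variable genes. Each point is 1 library, circles are Ppara-flox and squares PPARα-deficient hearts, and all PBS libraries lie at negative and all LPS libraries at positive scores on the first component.

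The first comparison asked how the genotypes differed in hearts given PBS. No group carried Cre without the deletion. Effects of the deletion and of Cre or its induction therefore cannot be told apart in any comparison between genotypes. PPARα-deficient hearts had lower transcript levels of genes for burning fatty acids. Decr1, which encodes an enzyme needed to oxidise unsaturated fatty acids (chromosome 4, 15917240 to 15945507, minus strand, protein coding), fell from 337 ± 35.6 to 126 ± 10.2 CPM (log2 fold change -1.42 ± 0.08 SE, adjusted p = 7.93e-08). Ucp3, a mitochondrial carrier of muscle, fell 5.29-fold (-2.40 ± 0.36 SE), the lipid droplet protein gene Plin5 fell 3.33-fold (-1.74 ± 0.21 SE) and Fbp2, the muscle form of fructose-bisphosphatase, fell 8.30-fold (-3.05 ± 0.31 SE). Of 20 measured genes of mitochondrial fatty acid oxidation 16 fell and none rose (18 fell when adjusted over the list alone), among them Acadvl (-1.16 ± 0.07 SE), Etfdh (-1.09 ± 0.08 SE) and the carnitine carrier gene Slc25a20 (-1.48 ± 0.11 SE). The list was lower than other genes (camera adjusted p = 3.7e-78, and adjusted p = 0.000281 with an estimated correlation). Of 27 measured PPARα target genes 17 fell (23 when adjusted over the list alone), including Hadha (-0.82 ± 0.06 SE). Camera gave adjusted p = 1.35e-73, and adjusted p = 0.00138 with an estimated correlation. Of 23 measured genes of lipid droplets and triglyceride metabolism 2 fell, Plin5 and the fatty acid binding protein gene Fabp3 (-0.75 ± 0.12 SE), and 7 fell when adjusted over the list alone (camera adjusted p = 9.11e-07, and adjusted p = 0.0448 with an estimated correlation).

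Ppara itself (chromosome 15, 85734983 to 85802819, plus strand, protein coding) fell from 50.2 ± 9.86 to 14.6 ± 2.58 CPM (log2 fold change -1.78 ± 0.28 SE, adjusted p = 0.00287). Over all 18713 genes tested, 75 were lower and 6 higher in PPARα-deficient hearts under PBS. The thioesterase genes Acot1 (-2.63 ± 0.26 SE) and Acot2 (-1.62 ± 0.14 SE), the desaturase gene Scd4 (-2.76 ± 0.34 SE) and Lgals4 (-2.21 ± 0.20 SE) were among the lowest, and Abat, a gene of GABA breakdown, rose (1.00 ± 0.13 SE). By far the highest fold belonged to Esr1, the estrogen receptor gene (chromosome 10, 4611593 to 5005614, plus strand, protein coding), at 0.225 ± 0.218 CPM in Ppara-flox and 3069 ± 150 CPM in PPARα-deficient hearts (13.73 ± 0.79 SE, adjusted p = 7.93e-08, and 14.51 without Ppara-flox PBS replicate 1). By edgeR, DESeq2 and limma-voom alike 0 of the 75 measured nuclear genes for subunits of oxidative phosphorylation and 0 of 21 genes of the tricarboxylic acid cycle passed (1 and 2 had an unadjusted p under 0.05). The same held for the 13 genes encoded by the mitochondrial genome (0 with an unadjusted p under 0.05). Camera called that list higher (median 0.18, adjusted p = 0.000211, and adjusted p = 0.89 with an estimated correlation). The 44 measured genes of inflammatory cytokines, chemokines and NF-kB targets had a median log2 fold change of 0.49 and 0 calls by edgeR over all genes, 14 with an unadjusted p under 0.05, 4 calls by DESeq2 and 0 by limma-voom (5 rose when adjusted over the list alone). Camera gave adjusted p = 0.000461, and adjusted p = 0.89 with an estimated correlation. In this list 1 library stood apart, PPARα-deficient PBS replicate 4, with a mean log2 CPM of 1.56 against 0.04 to 0.72 in the other 3 and -0.09 to 0.31 in Ppara-flox PBS libraries. Without it the median was 0.22 and camera gave adjusted p = 0.185, a test chosen after seeing the data. That library was also the highest PBS library in neutrophil markers, at -0.57 against -2.83 to -1.60. Calls over all genes were 2 without PPARα-deficient PBS replicate 2, and 1 without PPARα-deficient or Ppara-flox PBS replicate 1. The count of 5 adjusted over the list alone became 14 without PPARα-deficient PBS replicate 1, 17 without PPARα-deficient PBS replicate 2, 3 without Ppara-flox PBS replicate 2, and 2 without PPARα-deficient or Ppara-flox PBS replicate 4. Of 14 macrophage markers 0 passed by edgeR in either count, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05 (median 0.17, camera adjusted p = 0.0146, and adjusted p = 0.89 with an estimated correlation). DESeq2 called more genes, 48 higher and 137 lower, and a fit to these 8 libraries alone called 12 higher.

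**Figure D2:**
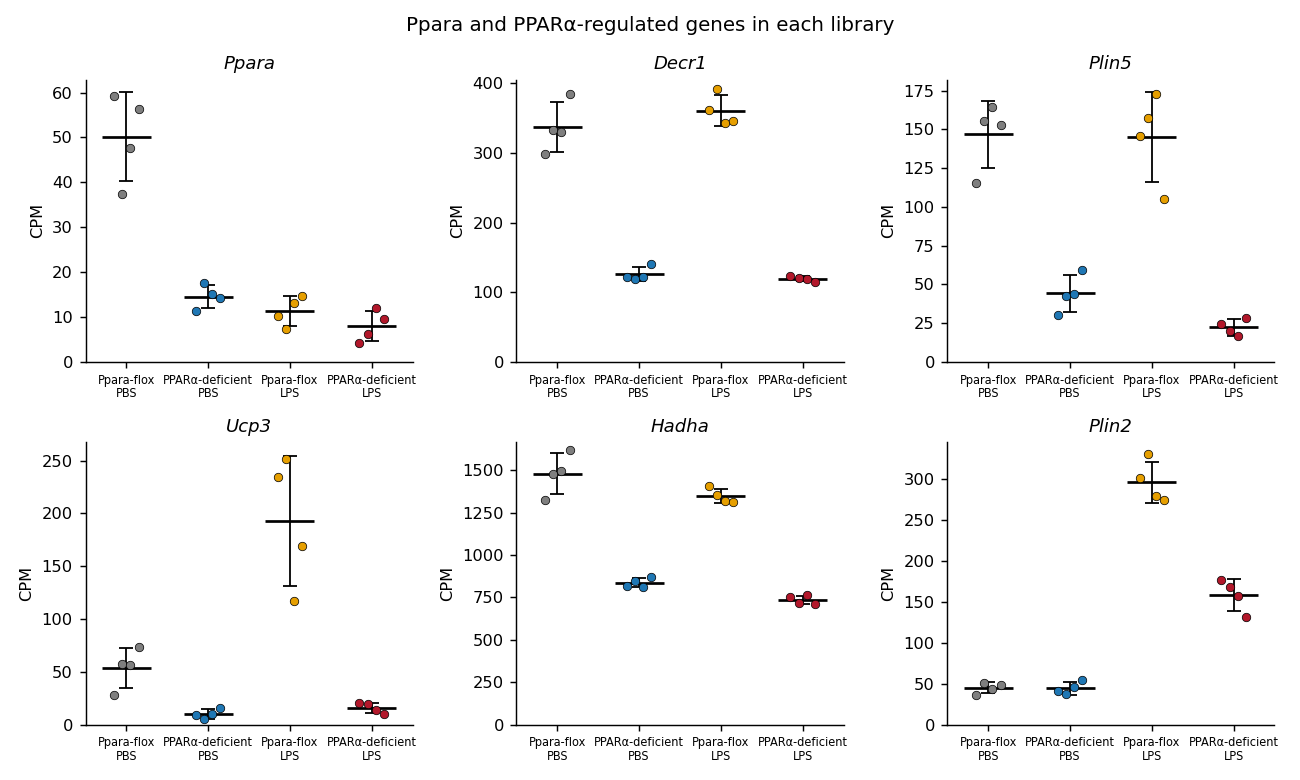
CPM of Ppara and of 5 genes regulated by PPARα in each of the 16 libraries, with 4 libraries per group; points are libraries, horizontal lines are means and error bars are SD. Decr1 lay between 115 and 141 CPM in all PPARα-deficient libraries and between 299 and 391 CPM in all Ppara-flox libraries.

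The second comparison asked what LPS did to Ppara-flox hearts. Lcn2, encoding the iron-trapping protein lipocalin 2 (chromosome 2, 32384633 to 32388252, minus strand, protein coding), rose from 2.56 ± 0.374 to 1620 ± 210 CPM (log2 fold change 9.31 ± 0.27 SE, 634-fold, adjusted p = 2.91e-12). Saa3, encoding an acute-phase serum amyloid A, rose from 0.035 ± 0.052 to 856 ± 195 CPM. Csf3, the gene of the neutrophil growth factor G-CSF, had 0 counts in all PBS libraries and 28.4 ± 8.86 CPM after LPS, at least 171-fold higher against a floor of 12 estimated counts (3 read pairs) per library. In the opposite direction, the myosin gene Myh7b fell from 193 ± 21.3 to 8.46 ± 1.45 CPM (-4.51 ± 0.18 SE) and Ppargc1a, a coactivator that drives mitochondrial biogenesis, fell from 399 ± 90.8 to 28.4 ± 8.79 CPM (-3.81 ± 0.38 SE, 14.1-fold). Ppara fell 4.44-fold to 11.3 ± 3.31 CPM (-2.15 ± 0.28 SE, adjusted p = 1.25e-05).

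Lists of immune genes differed in direction in Ppara-flox hearts. The list of immediate early genes, which also respond to dissection, rose in 12 of 16 cases with 1 lower by both counts (camera adjusted p = 0.000143, and adjusted p = 0.188 with an estimated correlation). Of 44 measured inflammatory genes 38 rose and 1, Ccl6, fell (39 and 1 when adjusted over the list alone, median log2 fold change 3.15, camera adjusted p = 1.44e-16, and adjusted p = 0.0816 with an estimated correlation). Of 36 interferon response genes 34 rose, over all genes and when adjusted over the list alone, including the interferon-induced GTPase genes Iigp1 (5.86 ± 0.35 SE) and Igtp (5.83 ± 0.35 SE). Their camera test gave adjusted p = 1.21e-16, and adjusted p = 0.146 with an estimated correlation. Neutrophil markers rose in 11 of 12 cases, counted both ways, with Hdc at 4.76 ± 0.28 SE and S100a8 at 4.69 ± 0.51 SE (adjusted p = 4.61e-06, and adjusted p = 0.133 with an estimated correlation). Macrophage markers went the other way, 9 of 14 lower and 1 higher by both counts, with Lyz2 at -2.21 ± 0.16 SE and Csf1r at -1.21 ± 0.12 SE (adjusted p = 0.00494, and adjusted p = 0.439 with an estimated correlation). Monocyte markers rose in 5 of 10 cases (5 higher and 1 lower when adjusted over the list alone; adjusted p = 0.0115, and adjusted p = 0.102 with an estimated correlation). Of 7 B cell markers 2 fell by both counts (median -0.74, adjusted p = 0.4). Of 11 T and NK cell markers 0 passed by edgeR, DESeq2 or limma-voom and 1 had an unadjusted p under 0.05. Of 16 genes of inflammasomes, pyroptosis and necroptosis 11 rose by both counts, among them Zbp1 (5.04 ± 0.36 SE), Mlkl (2.36 ± 0.23 SE) and Casp4 (2.90 ± 0.34 SE). The list had adjusted p = 0.000145, and adjusted p = 0.133 with an estimated correlation.

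Genes of contraction and energy metabolism fell in the same hearts. Of 24 genes of calcium handling and cardiac ion channels 17 fell and none rose (18 fell when adjusted over the list alone), including the potassium channel subunit gene Kcnip2 (-1.68 ± 0.11 SE), the phospholamban gene Pln (-1.11 ± 0.11 SE) and Casq2 (-1.36 ± 0.15 SE). Camera gave adjusted p = 8.45e-08, and adjusted p = 0.0816 with an estimated correlation. Of 20 sarcomere genes 17 fell and 1 rose by both counts, with cardiac actin Actc1 at -2.18 ± 0.18 SE and Myh6 at -0.88 ± 0.08 SE (adjusted p = 1.9e-07, and adjusted p = 0.133 with an estimated correlation). Of 21 genes of the tricarboxylic acid cycle 18 fell by both counts, with Idh3a at -0.56 ± 0.06 SE and Ogdh at -0.56 ± 0.06 SE (adjusted p = 7.28e-08, and adjusted p = 0.0816 with an estimated correlation). Nuclear genes of oxidative phosphorylation moved less, 36 of 75 fell (39 when adjusted over the list alone) with a median of -0.21 and Sdhd at -0.45 ± 0.07 SE. Their list call did not hold with an estimated correlation (adjusted p = 7.47e-08, and adjusted p = 0.451 with an estimated correlation). Of the 13 genes encoded by the mitochondrial genome 0 passed by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05, mt-Nd5 being the nearest (-0.24 ± 0.11 SE). Mitochondrial biogenesis, dynamics and quality control genes fell in 14 of 27 cases and 1 rose (17 and 2 when adjusted over the list alone), with Esrrg at -2.26 ± 0.19 SE, Mfn1 at -0.92 ± 0.06 SE and Bnip3 at 0.79 ± 0.12 SE (adjusted p = 0.000103, and adjusted p = 0.1 with an estimated correlation).

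Lipid genes were divided. Of 27 PPARα target genes 9 rose and 3 fell (9 and 4 when adjusted over the list alone), with the lipid droplet gene Plin2 up 6.59-fold (2.72 ± 0.14 SE). Acadm (-0.38 ± 0.07 SE) and Cpt1b (-0.34 ± 0.08 SE) fell. Of 20 genes of mitochondrial fatty acid oxidation 2 rose and 8 fell (2 and 9 when adjusted over the list alone), with Eci2 at 0.44 ± 0.07 SE and Hadh at -0.36 ± 0.07 SE. Camera called neither list (adjusted p = 0.142 for both). Fry called the target list higher (adjusted p = 0.0372) and did not call the oxidation list (0.0827). Glucose genes changed in both directions too, 4 of 21 higher and 11 lower by both counts, with Pfkfb3 at 3.26 ± 0.18 SE and the insulin-responsive transporter gene Slc2a4 at -1.40 ± 0.10 SE (adjusted p = 0.022, and adjusted p = 0.451 with an estimated correlation). Over all 18713 genes 3771 were higher and 3583 lower after LPS, of which 1511 and 1514 changed at least 2-fold. Every LPS library carried a higher number in its column header than every PBS library, so LPS could not be separated from the order in which animals were numbered.

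**Figure D3:**
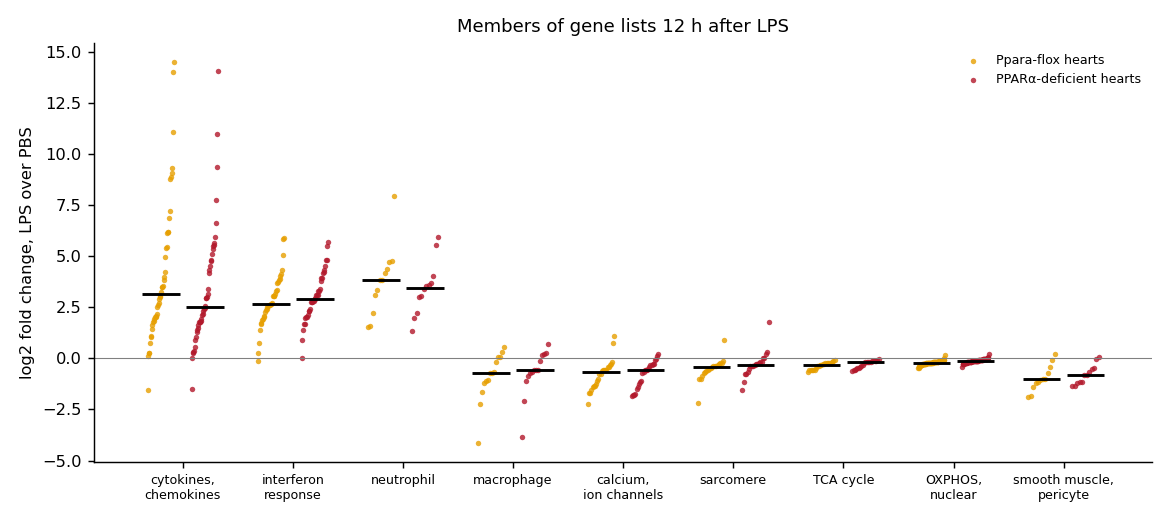
Log2 fold change between LPS and PBS of each measured member of 9 gene lists, in Ppara-flox and in PPARα-deficient hearts (4 libraries per group); points are genes and black bars are list medians. Medians of the cytokine and chemokine list were 3.15 and 2.51, and those of the calcium and ion channel list -0.68 and -0.59.

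The third comparison asked what LPS did to hearts whose cardiomyocytes lacked PPARα. Lcn2 rose 662-fold, from 2.43 ± 0.793 to 1608 ± 342 CPM (9.37 ± 0.28 SE, adjusted p = 2.73e-12). Saa3 reached 900.2 ± 352 CPM, and Csf3, with 0 counts in all PBS libraries, reached 29.2 ± 6.91 CPM, at least 181-fold higher against the same floor. Myh7b fell 20.6-fold (-4.36 ± 0.18 SE), the apelin receptor gene Aplnr fell 30.7-fold (-4.94 ± 0.25 SE) and Ppargc1a fell from 426 ± 85.4 to 61.7 ± 37.5 CPM. Esr1 counts fell from 3069 ± 150 to 83.4 ± 58.3 CPM (-5.20 ± 0.54 SE, adjusted p = 1.34e-06). Ppara fell to 7.99 ± 3.38 CPM (-0.87 ± 0.27 SE, adjusted p = 0.0188). This call rested on single libraries, with adjusted p = 0.0563 without PPARα-deficient PBS replicate 2, 0.0542 without PPARα-deficient LPS replicate 1 and 0.06 without PPARα-deficient LPS replicate 2.

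Immediate early genes rose in 9 of 16 cases by both counts (camera adjusted p = 0.000104, and adjusted p = 0.201 with an estimated correlation). Of 36 interferon response genes 35 rose by both counts (camera adjusted p = 1.33e-19, and adjusted p = 0.112 with an estimated correlation). Of 44 inflammatory genes 36 rose and 1 fell (37 and 1 when adjusted over the list alone; adjusted p = 8.64e-18, and adjusted p = 0.0832 with an estimated correlation). Neutrophil markers rose in 11 of 12 cases by both counts, with Hdc at 4.04 ± 0.27 SE (adjusted p = 3.74e-06, and adjusted p = 0.112 with an estimated correlation). Macrophage markers fell in 7 of 14 cases and 1 rose (8 and 1 when adjusted over the list alone), with Lyz2 at -2.08 ± 0.16 SE (adjusted p = 0.0242, and adjusted p = 0.563 with an estimated correlation). Calcium handling and ion channel genes fell in 15 of 24 cases by both counts, among them Kcnip2 (-1.74 ± 0.11 SE) and Atp2a2, the sarcoplasmic calcium pump gene (-0.58 ± 0.07 SE). The list had adjusted p = 5.12e-07, and adjusted p = 0.0832 with an estimated correlation. Of 20 sarcomere genes 13 fell and 1 rose by both counts, with Myh6 at -0.76 ± 0.08 SE and Mybpc3 at -0.77 ± 0.08 SE (adjusted p = 0.000451, and adjusted p = 0.309 with an estimated correlation). Tricarboxylic acid cycle genes fell in 13 of 21 cases (15 when adjusted over the list alone), with Dlat at -0.64 ± 0.07 SE (adjusted p = 3.74e-06, and adjusted p = 0.112 with an estimated correlation). Nuclear oxidative phosphorylation genes fell in 13 of 75 (6 when adjusted over the list alone; median -0.12, adjusted p = 0.000723, and adjusted p = 0.684 with an estimated correlation). Of 27 PPARα target genes 7 rose and 9 fell by both counts, with Plin2 up 3.56-fold (1.83 ± 0.13 SE), Pdk4, which restrains glucose oxidation, up 3.30-fold (1.72 ± 0.28 SE) and Plin5 at -0.99 ± 0.21 SE. Camera did not call the target list (adjusted p = 0.898), and neither did fry (0.613).

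Over all genes 3632 were higher and 3429 lower after LPS in PPARα-deficient hearts, of which 1432 and 1352 changed at least 2-fold. The responses of the genotypes overlapped: 2926 genes were higher in both, where 731.9 would be shared if the calls were independent. In addition 2750 were lower in both (656.6 if independent), and 2 were called in opposite directions. Across the 8737 genes called in either genotype the log2 fold changes had a Pearson r of 0.83, over genes, which are not independent replicates.

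The fourth comparison asked how the genotypes differed after LPS. Genes of fatty acid metabolism were lower in PPARα-deficient hearts here too. Ucp3 stood at 193 ± 61.7 CPM in Ppara-flox and 15.7 ± 4.87 CPM in PPARα-deficient hearts (-3.62 ± 0.38 SE, 12.2-fold, adjusted p = 2.82e-05). Plin5 stood at 145 ± 28.9 and 22.2 ± 5.26 CPM (-2.71 ± 0.22 SE, 6.53-fold), and Decr1 at 360.4 ± 22.3 and 119 ± 3.52 CPM (-1.59 ± 0.08 SE). Of 27 PPARα target genes 22 were lower and none higher (25 lower when adjusted over the list alone; camera adjusted p = 1.95e-77, and adjusted p = 0.00106 with an estimated correlation). Of 20 genes of mitochondrial fatty acid oxidation 16 were lower (19 when adjusted over the list alone), with Etfdh at -1.31 ± 0.08 SE and Hadha at -0.87 ± 0.06 SE (adjusted p = 8.7e-60, and adjusted p = 0.00106 with an estimated correlation). Lipid droplet genes were lower in 9 of 23 cases (12 when adjusted over the list alone), among them Fabp3 (-1.19 ± 0.12 SE), Dgat2, of triglyceride synthesis (-0.70 ± 0.09 SE), and Plin2 (-0.91 ± 0.13 SE). Camera gave adjusted p = 1.95e-14, and adjusted p = 0.00217 with an estimated correlation.

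Among the genes higher in PPARα-deficient hearts after LPS were 3 whose products lie at the Z-disc, which anchors the contractile filaments. They were picked from the called genes, and no list of Z-disc genes was tested. Synpo2l (chromosome 14, 20658946 to 20668354, minus strand, protein coding) stood at 61.2 ± 15.97 CPM in Ppara-flox and 272 ± 102 CPM in PPARα-deficient LPS hearts (2.15 ± 0.23 SE, adjusted p = 4.43e-05). Csrp3, encoding muscle LIM protein (chromosome 7, 48830398 to 48848033, minus strand, protein coding), stood at 383 ± 65.2 and 1097 ± 195 CPM (1.52 ± 0.14 SE, adjusted p = 1.09e-05). Flnc, encoding filamin C (chromosome 6, 29433256 to 29461883, plus strand, protein coding), stood at 342 ± 105 and 901 ± 256 CPM (1.40 ± 0.20 SE, adjusted p = 0.00103). Under PBS the genotypes lay at 148 ± 18.6 and 158 ± 15.2 CPM for Synpo2l, 766 ± 121 and 894 ± 62.5 CPM for Csrp3, and 629 ± 24.1 and 632 ± 34.0 CPM for Flnc. The sarcomere list as a whole had 2 higher members of 20 (5 when adjusted over the list alone), with a median of 0.10 and a mean of 0.24. Its call did not hold with an estimated correlation (adjusted p = 4.57e-05, and adjusted p = 0.311 with an estimated correlation). The leucine-rich repeat gene Lrtm1 was 2.93-fold higher (1.55 ± 0.26 SE). Esr1 stood at 0.228 ± 0.207 CPM in Ppara-flox and 83.4 ± 58.3 CPM in PPARα-deficient hearts (8.54 ± 0.69 SE, and 9.31 without Ppara-flox LPS replicate 2), a call that limma-voom did not make (adjusted p = 0.0596).

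**Figure D4:**
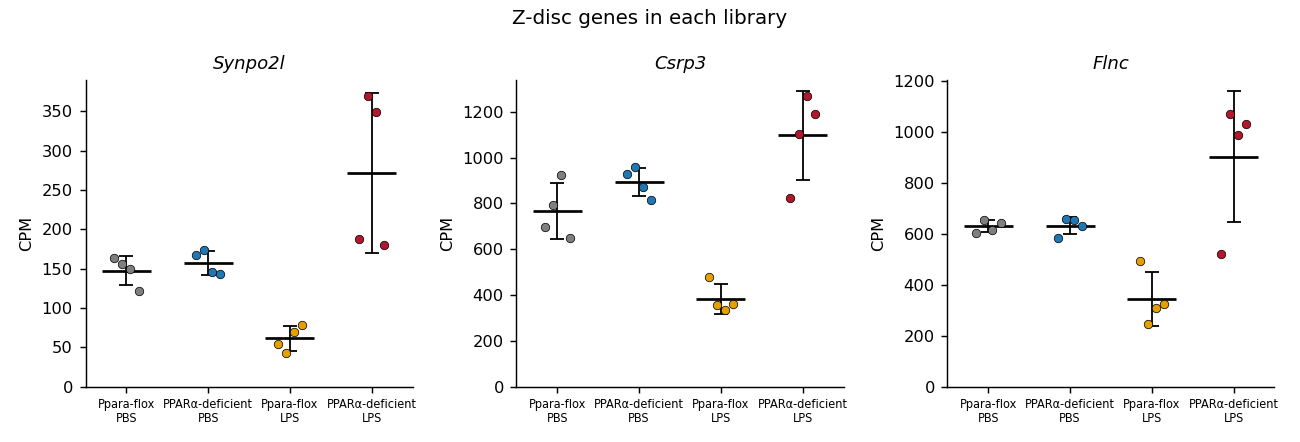
CPM of Synpo2l, Csrp3 and Flnc in each of the 16 libraries, with 4 libraries per group; points are libraries, horizontal lines are means and error bars are SD. Synpo2l and Csrp3 were higher in each PPARα-deficient LPS library (lowest 181 and 823 CPM) than in each Ppara-flox LPS library (highest 78.3 and 479 CPM).

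Ppara had a log2 fold change of -0.50 ± 0.27 SE between the genotypes after LPS (adjusted p = 0.651). Among 75 nuclear and 13 mitochondrially encoded genes of oxidative phosphorylation 0 passed by edgeR, DESeq2 or limma-voom. Camera called both lists higher (medians 0.06 and 0.19, adjusted p = 0.000776 and 0.00012, and 0.703 and 0.55 with an estimated correlation). It also called glycolysis (1.56e-05, 0 of 21 genes passing) and the cardiac stress programme (4.57e-05, 1 of 16) higher, at 0.214 and 0.18 with an estimated correlation. Camera called endothelial (0.00101, 1 of 13 passing), erythroid (0.00867, 0 of 8) and brown adipocyte markers (0.011, 1 of 6) lower. With an estimated correlation these 3 adjusted p-values were 0.311, 0.55 and 0.18. Of 44 inflammatory genes 0 passed by edgeR over all genes or when adjusted over the list alone, 3 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 and 1 (median log2 fold change 0.18, camera adjusted p = 0.0101, and adjusted p = 0.581 with an estimated correlation). The camera call ended without PPARα-deficient LPS replicate 2 (0.0607) or 3 (0.185, median 0.10), or without Ppara-flox LPS replicate 3 (0.181, median 0.12). Of 36 interferon response genes 0 passed by edgeR in either count, 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 1 and 0 (median 0.30, adjusted p = 0.000299, and adjusted p = 0.581 with an estimated correlation). In this list Ppara-flox LPS replicate 4 and PPARα-deficient LPS replicate 3 stood apart, with a mean log2 CPM of 6.50 and 6.88 against 5.39 to 5.82 and 5.75 to 6.06 in the others. The interferon call ended without PPARα-deficient LPS replicate 3 (adjusted p = 0.516, median 0.05) or Ppara-flox LPS replicate 3 (0.115, median 0.20), and held without both deviating libraries (2.81e-07, median 0.29). Without Ppara-flox LPS replicate 4 the median was 0.57 and 11 genes were higher when adjusted over the list alone, and without PPARα-deficient LPS replicate 4 1 gene passed in either count. Of 14 macrophage markers 0 passed by edgeR over all genes and 2 were higher when adjusted over the list alone, 5 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 1 and 0 (median 0.35, adjusted p = 6.02e-05, and adjusted p = 0.311 with an estimated correlation). Their mean log2 CPM was 3.70 and 3.52 in PPARα-deficient LPS replicates 3 and 4, against 3.12 and 3.13 in the other 2 and 2.93 to 3.20 in Ppara-flox LPS libraries. Without PPARα-deficient LPS replicate 3 the median was 0.21 and camera gave adjusted p = 0.00962, and without it and Ppara-flox LPS replicate 4 adjusted p = 0.0553 (median 0.19). The macrophage count of 2 became 0 without PPARα-deficient LPS replicate 3 or Ppara-flox LPS replicate 1, 1 without Ppara-flox LPS replicate 4, and 5 without PPARα-deficient LPS replicate 2, and 1 passed over all genes without Ppara-flox LPS replicate 3. These list tests without libraries were chosen after seeing the data. Over all genes 159 were lower and 72 higher in PPARα-deficient hearts. Of these, 63 were lower under PBS as well (0.6 if independent) and 3 were higher under both, Esr1, Abat and Epn3. Abat and Epn3 had log2 fold changes of 0.80 and 0.90 after LPS. The PBS call of Epn3 (adjusted p = 0.0279) ended without Ppara-flox replicate 1 (0.105), 3 (0.113) or 4 (0.0959) and without PPARα-deficient replicate 1 (0.0555), 2 (0.0669) or 4 (0.107). The count of 72 fell to 36 without Ppara-flox LPS replicate 1, 33 without Ppara-flox LPS replicate 2, 39 without PPARα-deficient LPS replicate 3 and 41 without PPARα-deficient LPS replicate 4. DESeq2 called 205 higher and 247 lower.

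**Figure D5:**
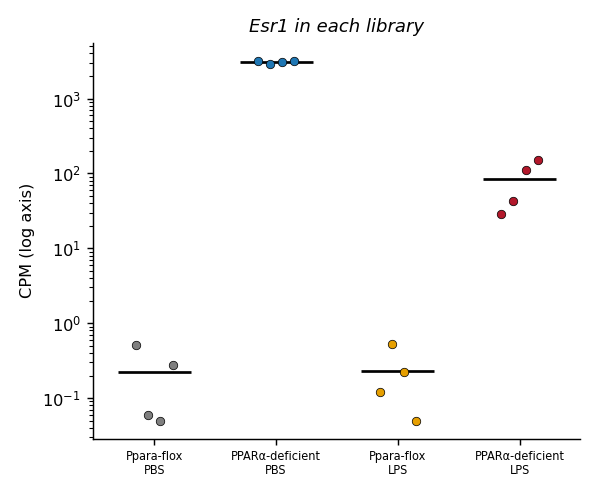
CPM of Esr1 on a log axis in each of the 16 libraries, with 4 libraries per group; points are libraries and horizontal lines are means. PPARα-deficient libraries lay at 2859 to 3201 CPM under PBS and 28.3 to 152 CPM after LPS, and no Ppara-flox library exceeded 0.52 CPM.

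The last comparison tested whether the response to LPS differed between genotypes. The smallest adjusted p-values were those of Synpo2l, whose fold change with LPS was higher in PPARα-deficient hearts by 2.06 ± 0.32 SE on the log2 scale, and of Csrp3, higher by 1.29 ± 0.20 SE, each with adjusted p = 0.0696 by edgeR. Synpo2l was chosen here after its values were seen. With all 16 libraries both passed by DESeq2 (2.84e-06 for Synpo2l and 1.46e-05 for Csrp3), with the stricter filter (0.0473), with counts divided by 4 (0.0456) and with bias-adjusted deviances (0.0462), the last 2 chosen after seeing the data. Neither passed with RLE (0.0723) or upper-quartile factors (0.0651), without a filter (0.0912) or with the replicate number as a block (0.271). Among settings chosen after seeing the data, neither passed by limma-voom (0.0561), with the PBS number series as a block (0.116) or without mitochondrial genes (0.0662). Csrp3 also passed without PPARα-deficient LPS replicate 1 (adjusted p = 0.0142) and without Ppara-flox LPS replicate 1 (0.0276), and Synpo2l without PPARα-deficient LPS replicate 1 (0.0164) and replicate 4 (0.021). For both genes the other fits without 1 library gave 0.0579 to 0.163. Without Ppara-flox LPS replicate 4 and PPARα-deficient LPS replicate 3 together, also chosen after seeing the data, Synpo2l passed (0.0496) and Csrp3 did not (0.119). Among PPARα target genes Plin2 had an interaction of -0.89 ± 0.18 SE (adjusted p = 0.201), and Ppara one of 1.28 ± 0.38 SE (adjusted p = 0.599).

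No gene passed the interaction test by edgeR quasi-likelihood, where 1075 of 18713 had an unadjusted p under 0.05, and none by limma-voom, while DESeq2 called 24 higher and 30 lower. Without 1 library the edgeR counts were 3 higher and 1 lower (PPARα-deficient LPS replicate 1), 1 and 1 (PPARα-deficient LPS replicate 4), 1 and 0 (Ppara-flox LPS replicate 1), and 0 and 1 (PPARα-deficient PBS replicate 4 or PPARα-deficient LPS replicate 3). Of 27 PPARα target genes 0 passed by edgeR over all genes, 6 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0, and 4 were lower when adjusted over the list alone (median -0.11, camera adjusted p = 0.00143, and adjusted p = 0.953 with an estimated correlation). Of 23 lipid droplet genes 0 passed, 6 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0, and 3 were lower when adjusted over the list alone (median -0.19, adjusted p = 0.000287, and adjusted p = 0.576 with an estimated correlation).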

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

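The list tests of the interaction were fixed before the data were examined. The counts over other splits of the libraries and the tests of explanations were written down after the results were seen.

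Splitting the same 8 libraries in other ways gave fewer calls than the real grouping in each comparison of 2 groups. For LPS in Ppara-flox hearts 1 of the 35 splits, the real one, called as many as 7354 genes, and the highest other called 1. For LPS in PPARα-deficient hearts it was 1 of 35, with 7061 genes against 1. For the genotypes under PBS it was 1 of 35, with 81 genes against 1, and for the genotypes after LPS 1 of 35, with 231 genes against 35. A true difference adds to the spread within mixed splits and lowers their calls. With only 35 splits as well, these 4 counts do not by themselves exclude chance. At an unadjusted p under 0.05 the highest other split held 1711 genes against the real 1042 under PBS, and 1952 against 1709 after LPS. For LPS it held 3411 against 8758 in Ppara-flox and 2912 against 8548 in PPARα-deficient hearts. For the interaction, 22 of 100 splits, the real one included, held at least 1075 genes with an unadjusted p under 0.05. The real split held 1075 and the highest other 1866, so chance cannot be excluded. Drawn splits can carry part of the genotype difference shared by both treatments, so they are no clean reference for chance. A drawn split that exchanged the genotypes among the LPS libraries alone called 262 genes, which is the structure left by the genotype difference shared by both treatments.

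A library stood far from the rest of its group in 2 of 84 group values tested, where chance gives about 1 in 20. Decr1 was 141 CPM in PPARα-deficient PBS replicate 4 and 119 to 122 CPM in the other 3. Flnc was 520.1 CPM in PPARα-deficient LPS replicate 1 and 986 to 1070 CPM in the other 3. Over all 157 named genes this held in 46 of 628 groups (7.3%), at most 5 of them in any 1 library.

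Camera at its preset correlation called 7 lists whose LPS response differed between genotypes. The adjusted p was 7.44e-05 for nuclear genes of oxidative phosphorylation (median interaction 0.08), 0.000287 for lipid droplets (-0.19), 0.000287 for the sarcomere (0.12), 0.00143 for PPARα targets (-0.11), 0.00628 for glycolysis (0.13), 0.0118 for erythroid markers (-1.51) and 0.014 for the cardiac stress programme (0.36). With an estimated correlation the 7 adjusted p-values lay between 0.576 and 0.953, and with fry between 0.534 and 0.97.

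Esr1 counts stood at 3069 CPM in PPARα-deficient PBS hearts and at 0.52 CPM or less in each Ppara-flox library. RNA from another tissue or a mixed library would bring other abundant transcripts, and the highest gain among the other genes called higher was 22.2 CPM (Epn3). Ppara-flox LPS hearts, whose Ppara level was as low as under the deletion, held 0.228 CPM of Esr1. In these hearts a low Ppara transcript did not bring Esr1 with it. Their Ppara had been low only since the injection, however, and LPS also lowered Esr1 in PPARα-deficient hearts, to a mean of 83.4 CPM. The comparison therefore cannot decide whether a lasting loss of Ppara raises Esr1. Another candidate explanation left open is reads of a Cre transgene that carries part of the Esr1 coding sequence, as in hormone-inducible Cre fusions. The 15 measured genes within 1 Mb of Esr1 had a median log2 fold change of 0.105, so its neighbours did not rise with it. That speaks against a rise of the whole locus only. A rise of Esr1 alone at its own locus would leave the neighbours unchanged too. The labels do not name the Cre line, and counts per gene symbol cannot show which part of Esr1 was read.

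The Esr1 counts of PPARα-deficient hearts fell with LPS, to 28.3 to 152 CPM. The log2 fold change lay -4.44 ± 0.55 SE from that of Myh6, so Esr1 did not follow the level of this cardiomyocyte transcript. A transcript that is lost faster than Myh6 once its promoter is less active may still explain the fall, and was not tested. A second source of mice cannot be told apart from LPS here, since 0 of the LPS libraries had a header number within the PBS range. The 2 number series among the PBS libraries did not differ in this way, with Esr1 at 3150 and 2859 CPM in replicates 1 and 2 and at 3068 and 3201 CPM in replicates 3 and 4, which says nothing of the LPS series.

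Synpo2l, Csrp3 and Flnc were higher in PPARα-deficient hearts after LPS, by 1.397 to 2.15 on the log2 scale. A higher share of cardiomyocyte RNA would raise sarcomere genes alike, but the 19 other measured members had a median of 0.094 and an upper quartile of 0.145. The calls of the 3 genes did not rest on the pair of LPS libraries that deviated together, as their highest adjusted p without both was 0.0154. The pair holds a library of each genotype, so a deviation that both share would tend to cancel between the genotypes. Whether the genotype changes the response of these genes to LPS stays open, as a hypothesis: the interaction adjusted p was 0.0696, 0.0696 and 0.192 (range over all alternatives 2.84e-06 to 0.421), so a changed response and none cannot be told apart. It passed by DESeq2 for all 3 (2.84e-06, 1.46e-05 and 0.00249), for Synpo2l and Csrp3 also with 3 other settings (0.0456 to 0.0473), without the deviating pair for Synpo2l alone (0.0496), without PPARα-deficient LPS replicate 1 for all 3 (0.0164, 0.0142 and 0.0164), without PPARα-deficient LPS replicate 4 for Synpo2l (0.021) and without Ppara-flox LPS replicate 1 for Csrp3 (0.0276). In most settings it passed for none of the 3, among them RLE factors (0.0723 to 0.189) and no filter (0.0912 to 0.291). The same held by limma-voom (0.0561 to 0.173), with the replicate block (0.271 to 0.406) and in most fits without 1 library.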

How the results depend on the processing

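No called fold change of a named gene changed sign under any alternative. Of 234 called fold changes of named genes 214 kept their call under every alternative, and counts over all genes tested that are not given here stayed within 1.5 times those reported. Alternatives marked "added" were chosen after seeing the data, and the cause of a change was not tested except where the setting itself is stricter or tests fewer genes or libraries. Requiring at least 2-fold left 1511 and 1514 genes higher and lower for LPS in Ppara-flox hearts, 1432 and 1352 in PPARα-deficient hearts, 33 lower for the genotypes under PBS, and 18 and 62 after LPS. An adjusted p under 0.01 left 2 higher under PBS and 18 higher after LPS. Of the LPS calls 51.3% in Ppara-flox and 51.4% in PPARα-deficient hearts were higher, a share that became 45.4% and 46.5% with upper-quartile factors and 49.9% and 50.7% with RLE factors. DESeq2 called 48 and 137 under PBS, 205 and 247 after LPS and 24 and 30 for the interaction, and the cause was not tested. The 72 genes higher in PPARα-deficient hearts after LPS became 44 without a filter, 25 in a fit to the 8 libraries (12 in place of 6 under PBS), 44 without Ppara-flox LPS replicate 4 and PPARα-deficient LPS replicate 3 (added), and 33 to 79 over leaving out 1 library. The replicate number did not pair the libraries (residual correlations of -0.203 to 0.162); with it as a block the count was 45 higher. The interaction, with 0 and 0, became 3 and 1 with the stricter filter, 3 and 1 with counts divided by 4 (added), 2 higher with bias-adjusted deviances (added), 1 and 4 without the 2 libraries (added), and 0 to 3 and 0 to 1 over leaving out 1 library. With an estimated correlation the lists called fell from 19 to 0 and 18 to 0 for LPS, from 8 to 3 and from 14 to 3 for the genotypes under PBS and after LPS, and from 7 to 0 for the interaction; with fry they were 26 and 23 for LPS and 4, 3 and 0 for the others. Without PPARα-deficient PBS replicate 4 (added) the inflammatory list lost its call under PBS (adjusted p = 0.185), and it kept it without any other PBS library (2.6e-07 to 0.00373). After LPS (all added) the adjusted p ranged over leaving out 1 library from 0.000293 to 0.185 for this list, 5.23e-11 to 0.516 for interferon and 1.13e-06 to 0.00962 for macrophage markers, and was 0.155, 2.81e-07 and 0.0553 without the 2 libraries. Blocking on the 2 number series of the PBS libraries or leaving out mitochondrial genes (both added) moved no count of genes by more than 1.5 times. If a read pair counts as about 4, some 16392284 to 18859006 read pairs per library limit genes with few counts. The floor used, 12 estimated counts, was on average 0.166 CPM in Ppara-flox and 0.162 CPM in PPARα-deficient PBS libraries, without TMM scaling.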

Other observations

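LPS also moved genes of other cell types and of stress hormones. In Ppara-flox hearts 12 of 17 glucocorticoid-responsive genes rose and 2 fell (13 and 2 when adjusted over the list alone; camera adjusted p = 5.24e-06, and adjusted p = 0.133 with an estimated correlation), with the metallothionein gene Mt1 at 3.32 ± 0.16 SE (n = 4 per group). In PPARα-deficient hearts 10 of 17 rose by both counts, with Fkbp5, a chaperone of the glucocorticoid receptor, at 2.61 ± 0.16 SE (adjusted p = 3.24e-06, and adjusted p = 0.112 with an estimated correlation). Markers of smooth muscle and pericytes fell in 10 of 12 cases in Ppara-flox and 9 of 12 in PPARα-deficient hearts by both counts, with Rgs5 at -0.999 ± 0.08 SE and -1.21 ± 0.08 SE, and with adjusted p = 1.88e-05 and 8.11e-05 (adjusted p = 0.133 and adjusted p = 0.112 with an estimated correlation). Extracellular matrix genes fell in 15 of 23 cases and 4 rose in Ppara-flox hearts (16 and 4 when adjusted over the list alone), with Col6a3 at -1.94 ± 0.18 SE and the cross-linking enzyme gene Lox at 2.96 ± 0.23 SE (adjusted p = 0.000697, and adjusted p = 0.451 with an estimated correlation). In PPARα-deficient hearts 14 matrix genes fell and 4 rose (15 and 4 when adjusted over the list alone; adjusted p = 0.00859, and adjusted p = 0.601 with an estimated correlation). Fibroblast markers fell with them, in 6 of 12 cases with 1 higher in each genotype (7 and 1 in Ppara-flox and 6 and 1 in PPARα-deficient hearts when adjusted over the list alone), with adjusted p = 0.00215 and 0.00543 (adjusted p = 0.217 and adjusted p = 0.294 with an estimated correlation).

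Chrna2, a subunit gene of a nicotinic acetylcholine receptor, lay below the level set for named genes and was chosen after its values were seen. It stood at 2.03 ± 0.959 CPM in Ppara-flox and 0.0282 ± 0.0326 CPM in PPARα-deficient PBS hearts (adjusted p = 0.000878 by edgeR), and at 2.89 ± 1.03 and 0.0165 ± 0.033 CPM after LPS (adjusted p = 0.000171), with n = 4 per group.

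LPS lowered Ppara in Ppara-flox hearts to 11.3 CPM, near the 14.6 CPM of PPARα-deficient PBS hearts, and the hypothesis that this fall lowers the receptor's target genes as the deletion does was tested after the result was seen. The 27 measured targets had a median log2 fold change of 0.10 with LPS in Ppara-flox hearts (mean 0.41), against -0.82 for the genotypes under PBS, so at 12 h the values do not show such a fall. The protein and its activity were not measured. Counts per gene symbol in heart tissue cannot show which part of Ppara was read, or in which cells. Similar Ppara counts therefore need not mean a similar loss of the receptor in cardiomyocytes.

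In Ppara-flox LPS replicate 4 and PPARα-deficient LPS replicate 3, whose header numbers are adjacent, interferon response genes had a mean log2 CPM of 6.50 and 6.88, against 5.39 to 5.82 and 5.75 to 6.06 in the other 3 libraries of each group. Mitochondrial rRNA, a sign of RNA quality or selection, took 1.07% and 0.856% of their counts, against 0.385% to 0.467% and 0.422% to 0.604% in the others, and 0.487% to 0.869% in PBS libraries. Their inflammatory lists stood at 4.09 and 4.44, against 3.83 to 4.22 and 4.00 to 4.27. The 27 lines with symbols turned into dates by a spreadsheet held 0.0644% to 0.0861% of the counts and were not tested.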
